A study of Mus musculus with 3 samples.

How the data were processed

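Gene expression was compared among 3 populations of Flk1+ cells sorted from embryoid bodies, which are aggregates of differentiating mouse embryonic stem (ES) cells of the line named BRC6 in the labels. The embryoid bodies had been cultured for 7 days. Flk1 is the receptor tyrosine kinase encoded by Kdr and is used as a mesoderm marker. PDGFRα is a platelet-derived growth factor receptor, and CAR is the coxsackievirus and adenovirus receptor, a junctional adhesion protein. The populations were PDGFRα−CAR−, PDGFRα−CAR+ and PDGFRα+CAR+, all Flk1+. Per the series description, RNA of 5 separate experiments was pooled before labelling, so each population is represented by 1 pool. Each pair of populations was hybridised once, which gives 3 two-colour arrays. No dye was swapped: PDGFRα−CAR− RNA always carried Cy5 and PDGFRα−CAR+ RNA always carried Cy3. PDGFRα+CAR+ RNA carried Cy3 against PDGFRα−CAR− RNA and Cy5 against PDGFRα−CAR+ RNA.

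Per the file headers, the arrays were TORAY mouse chips read at 635 and 532 nm, and the ratios in the scanner tables are 532 over 635. The deposited scanner tables hold the median pixel intensity of each spot and of its surroundings in both channels, with no normalisation or background step recorded in the header. Each array had 23474 probe spots for 23473 distinct probes, 2736 blank spots, 1102 spots marked as holding no probe, and positive and negative control spots. The authors also deposited 1 normalised log2 ratio per probe and array. The labels give its direction, and its method is not given in the sources used here. Set against the scanner signals, these log2 values followed Cy3 over Cy5 after subtraction of the blank-spot level. Over the brighter probes the slopes on that ratio were 0.996, 0.996 and 0.997. The column medians were 4e-05, -5e-05 and 3e-06. The constant removed per array was similar for bright probes (1.23, 0.88 and 1.39) and dim probes (1.26, 0.90 and 1.42). This describes 1 scaling factor per array and no intensity-dependent step. Direction and log base are thereby known, and the exact background level is not.

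All ratios in the report, except where the authors' values are named, were computed from the scanner intensities. Spot intensities were background-corrected with the normexp method (offset 50) in limma 3.58.1 under R 4.3.3. They were then normalised by loess within each array, with control and flagged spots (2 per array) given no weight. The local background around each spot was not used. It followed the spot itself, with correlations of log signal and log background of 0.908 to 0.969. This choice and the percentile for detection below were made after the files had been inspected and before any probe was counted. The offset understates the ratios of dim probes. Log2 ratios are Cy3 over Cy5, as in the labels. A probe counted as above background in a population when its signal exceeded the 97.5th percentile of the blank spots and of the no-probe spots on both arrays that held that population.

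The 3 arrays form a closed loop, so each log2 ratio can be read directly from 1 array and indirectly from the other 2. The loop residual is the indirect minus the direct ratio of PDGFRα−CAR+ to PDGFRα−CAR− RNA. It holds the noise of the 3 arrays and any dye effect specific to a probe. Subtracting it from a direct ratio gives a ratio free of a constant dye effect, here called the dye-free ratio. A probe was counted as at least 2-fold higher or lower when the direct and the dye-free ratio both reached 1 in size on the log2 scale, in the same direction, and it was above background in at least 1 of the populations compared. With 1 pool per population and 1 array per comparison there is no spread between independent samples. No p-value is therefore given, and no count is a statistical test. The only error available is the technical noise from the loop residual. Because array 1 and array 2 of the loop were scanned in the first run and the array of the 2 CAR+ populations in the second, the run is confounded with that direct comparison. Its indirect route uses the first run alone.

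The scripts were tested on simulated spots with 200 changed probes in each CAR+ pool. The noise was normally distributed, with the robust spread of the loop residual over the brighter probes. Changed probes were drawn only from probes well above background, so recovery among dim probes was not tested. For PDGFRα+CAR+ over PDGFRα−CAR− cells, with 14786 probes in the step, 0 of 27 simulated 2-fold increases, 35 of 35 simulated 3-fold increases and 35 of 35 simulated 4-fold increases were counted. For decreases, the numbers were 3 of 35 at 2-fold, 24 of 36 at 3-fold and 26 of 32 at 4-fold. The rule is thus strict for true 2-fold differences. With no simulated difference, 4, 0 and 0 probes were counted in the 3 comparisons.

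No file or table used here pairs the probe identifiers with genes. The gene lists and the rule for named genes that had been fixed before the data were examined (6 probes per direction, the sorted proteins and list members) could not be applied, and no gene is named. Only 4 probe identifiers are given, the 2 highest and 2 lowest of the comparison between PDGFRα+CAR+ and PDGFRα−CAR− cells under the ranking of that rule. For the same reason the levels of the sorted proteins' own transcripts could not be checked against the labels. Alternatives covered background correction, normalisation, the filter on dim probes, the choice of route around the loop and the authors' deposited ratios. The groups of probes shared or set apart, and the position of the PDGFRα−CAR+ pool between the others, were chosen as results after the data had been examined. Figures were drawn with matplotlib 3.10.9.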

Results

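Total RNA from 3 pools of sorted Flk1+ cells was compared on 3 two-colour arrays, 1 for each pair of populations. Each pool combined RNA of 5 experiments and there was 1 array per comparison, so no replicate error exists for any value below. The number of arrays limits the precision. Of 23473 probes, 12666 were above background in PDGFRα−CAR− cells, 15571 in PDGFRα−CAR+ cells and 14100 in PDGFRα+CAR+ cells. A total of 12155 probes were above background in all 3 populations, and 5798 were below it in all of them. The order of the populations cannot be separated from dye, array and scan run. The PDGFRα+CAR+ pool itself had 66.3% of probe spots above background in Cy3 on its first-run array and 60.7% in Cy5 on its second-run array. PDGFRα−CAR− RNA was seen in Cy5 alone and PDGFRα−CAR+ RNA in Cy3 alone.

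Technical error was small beside the differences between populations. Over the 12153 probes measured in all pools on every array, the direct log2 ratio of PDGFRα−CAR+ to PDGFRα−CAR− RNA and the ratio obtained through PDGFRα+CAR+ RNA had a Pearson r of 0.949. This correlation is across probes, which are not independent replicates. The loop residual had a median of 0.03 and lay within 0.5 of 0 for 99.5% of probes. It corresponded to a technical SD of 0.083 per log2 ratio (robust estimate). The SD of the log2 ratios over the same probes was 0.47 for PDGFRα−CAR+ over PDGFRα−CAR−, 0.70 for PDGFRα+CAR+ over PDGFRα−CAR− and 0.45 for PDGFRα−CAR+ over PDGFRα+CAR+. The error covers hybridisation, spots and a constant dye effect of a probe, and it does not cover differences between cultures or sorts. A labelling error common to both arrays of the PDGFRα−CAR− pool, or of the PDGFRα−CAR+ pool, would also cancel out of it.

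**Figure D1:**
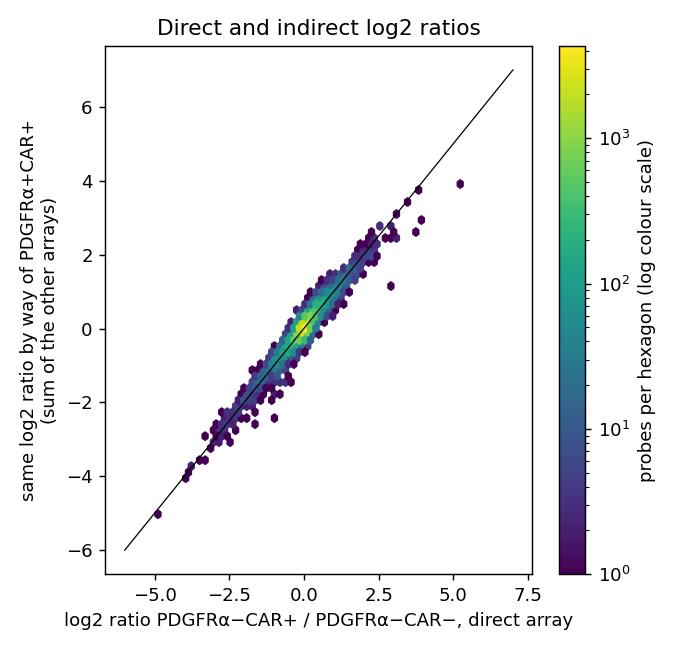
Log2 ratio of PDGFRα−CAR+ to PDGFRα−CAR− RNA on the direct array (horizontal axis) against the sum of the log2 ratios of the other arrays, which pass through PDGFRα+CAR+ RNA (vertical axis). Colour gives the number of probes per hexagon on a log scale, the line marks equality, probes below background are drawn too, and the 12153 probes measured in all pools had r = 0.949.

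The first comparison asked how CAR+ and CAR− cells differ among Flk1+PDGFRα− cells. In PDGFRα−CAR+ cells 369 probes were at least 2-fold higher and 323 at least 2-fold lower than in PDGFRα−CAR− cells, out of 15655 probes above background in either population. Differences of at least 4-fold were found for 48 probes in the higher direction and 67 in the lower. At least 8-fold differences numbered 9 and 12. Among the counted probes the median log2 ratio was 1.34 for those higher and -1.50 for those lower in CAR+ cells. Most probes differed little, with 83.5% of them within 0.5 of 0 on the log2 scale. Of the probes higher in CAR+ cells, 62 were below background on both arrays in CAR− cells, whereas 4 probes showed the reverse. Dye and population cannot be told apart in that contrast, since the CAR+ pool carried Cy3 and the CAR− pool Cy5 on every array. The balance of higher to lower probes depended on how the arrays were centred. It was 53.3% higher with loess and 53.7% higher in the authors' ratios. It was 68.7% higher (379 against 173) when each array was only centred on the median of its probe spots. That centring left the probes measured in all pools with a median log2 ratio of 0.38. Its loop residual had a median of 0.42, against 0.03 with loess and 0.01 in the authors' ratios. A difference between populations cancels around the loop, so median centring left an offset of Cy3 over Cy5 in these probes. The balance of 68.7% therefore argues for no shift between the populations.

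The second comparison set PDGFRα+CAR+ cells, which differ in both sorted proteins, against PDGFRα−CAR− cells. In PDGFRα+CAR+ cells 788 probes were at least 2-fold higher and 674 at least 2-fold lower, out of 14599. At least 4-fold differences were found for 230 probes in the higher and 203 in the lower direction, and at least 8-fold differences for 67 and 69. On/off differences were more frequent here. Among the counted probes 185 were above background in PDGFRα+CAR+ cells and below it in PDGFRα−CAR− cells, and 110 showed the reverse. The PDGFRα−CAR− pool was measured in Cy5 alone, so dye and population are not separated in these numbers. The number of counted probes was 1462, against 692 between the PDGFRα− populations and 574 between the CAR+ populations. It was the largest of the 3 in 12 of the 13 settings, the one reported here included. The settings use the same arrays and some repeat each other, so they are not separate checks. The exception was subtraction of the local background, where 2731 probes were counted here and 3459 between the PDGFRα− populations.

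The 2 probes ranked highest and the 2 ranked lowest in PDGFRα+CAR+ relative to PDGFRα−CAR− cells had intermediate levels in PDGFRα−CAR+ cells. Probe M200004673 had a log2 ratio of 6.39 for PDGFRα+CAR+ over PDGFRα−CAR− cells, 5.28 for PDGFRα−CAR+ over PDGFRα−CAR− cells and -2.55 for PDGFRα−CAR+ over PDGFRα+CAR+ cells. Its loop residual was -1.43, so its size is known only roughly. The second of the higher probes, M300004916, had log2 ratios of 5.88, 2.54 and -3.92 in the same order, with a residual of -0.58. In PDGFRα−CAR− cells the signals of M200004673 were 58 and 132 and those of M300004916 were 38 and 66, where background ended at 29 and 35. Among the probes lower in PDGFRα+CAR+ cells, M200016163 had log2 ratios of -5.87, -3.78 and 2.11, and its residual was 0.018. Probe M300004395 had log2 ratios of -5.39, -2.97 and 2.46, with a residual of 0.040. The PDGFRα+CAR+ signals of these 2 probes were low, at 48 and 109 for M200016163 and 61 and 156 for M300004395, where background ended at 26 and 76. All 4 probes kept their direction in every setting tried, but the sizes of the ratios depended on background correction and normalisation. For the 2 higher probes the sizes also depended on the route around the loop, while for the 2 lower probes no route moved a ratio by more than the technical SD. For M200004673 the ratio of -2.55 was -1.11 by the indirect route, and that of 5.28 ranged from 3.85 (indirect) to 6.71 (dye-free). For M300004916 the ratio of 2.54 fell to 1.05 with local background used in normexp, and that of 5.88 ranged from 3.93 to 8.64. The genes these probes detect are not given in the sources used here.

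The third comparison asked how PDGFRα− and PDGFRα+ cells differ among Flk1+CAR+ cells. In PDGFRα−CAR+ cells 296 probes were at least 2-fold higher and 278 at least 2-fold lower than in PDGFRα+CAR+ cells, out of 15824. At least 4-fold differences were found for 69 probes in the higher direction and 30 in the lower. Within 0.5 of 0 lay 86.2% of probes, the largest such share of the 3 comparisons with loess normalisation. The direct array was scanned in another run than the other 2. The indirect route, from the arrays of the first run alone, gave 335 higher and 311 lower. Median centring moved the share of higher probes from 51.6% to 76.8% (436 against 132), and left the probes measured in all pools with a median log2 ratio of 0.47. As in the first comparison, the offset of Cy3 over Cy5 left by that centring enters this share. In the authors' ratios the share was 57.3%.

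**Figure D2:**
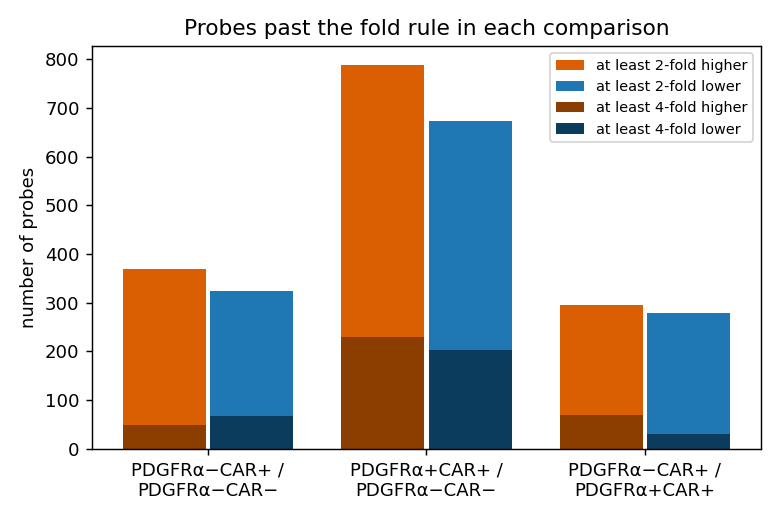
Number of probes (vertical axis, from 0) at least 2-fold higher or lower in each comparison, with those at least 4-fold different in the darker lower part of each bar. Each bar rests on 1 pool per population; the comparison of PDGFRα+CAR+ with PDGFRα−CAR− cells had the most, 788 higher and 674 lower.

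The differences of the 2 CAR+ populations from CAR− cells overlapped. Of the probes higher in PDGFRα−CAR+ than in PDGFRα−CAR− cells, 306 were also at least 2-fold higher in PDGFRα+CAR+ cells, which is 83.2% of the 368 that could be compared. Of the 323 lower probes, 290 (89.8%) were also lower in PDGFRα+CAR+ cells. In the opposite direction, 9 probes were higher in PDGFRα−CAR+ and lower in PDGFRα+CAR+ cells, each against PDGFRα−CAR− cells. Both comparisons use the same PDGFRα−CAR− pool, which by itself makes the lists overlap, and its part in the overlap was not determined. The arrays gave an r of 0.782 between the 2 log2 ratios. A simulation of array noise alone gave 0 shared probes and an r of 0.0244. It holds no difference between pools, so it shows only that array noise does not produce the overlap. It cannot show what unrelated pools set against the same PDGFRα−CAR− pool would give. No relation between the CAR+ populations is read from the r of 0.782. The log2 ratios of PDGFRα−CAR+ over PDGFRα−CAR− and over PDGFRα+CAR+ cells both hold the PDGFRα−CAR+ pool. Unrelated pools would therefore give a positive r between them. Over the 12153 probes measured in all pools it was -0.178. Among dim, middle and bright probes (4051 each) it was -0.05, -0.17 and -0.23. These values argue against unrelated pools for these probes, without showing which pools are related. With median centring, which left an offset of Cy3 over Cy5, the shared higher and lower probes numbered 263 and 157. In the authors' ratios they numbered 579 and 499, so the counts depend on processing. The shared probes were chosen on these same arrays, so the direction of their signal shares from CAR− to CAR+ pools follows from the choice. The 306 shared higher probes made up 0.63% of the probe signal in PDGFRα−CAR− cells on both of its arrays. They made up 2.16% and 2.48% in PDGFRα−CAR+ cells, and 4.64% (Cy5) and 5.34% (Cy3) in PDGFRα+CAR+ cells. The 290 shared lower probes fell in the reverse order, with 3.12% and 3.14%, then 0.71% and 0.79%, then 0.48% and 0.56%.

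Most probes that separated PDGFRα+CAR+ from PDGFRα−CAR− cells had a level in between in PDGFRα−CAR+ cells. Of 565 higher probes measured in all pools, 94.2% had an intermediate level, as had 408 of 512 lower probes (79.7%). Probes chosen for a large difference between 2 pools mostly place another pool in between, and no reference for these shares was computed. On the log2 scale, with PDGFRα−CAR− cells at 0 and PDGFRα+CAR+ cells at 1, the median position of PDGFRα−CAR+ cells was 0.55 for the higher probes. The quartiles were 0.41 and 0.71. For the lower probes the median was 0.53, with quartiles of 0.27 and 0.78. Over all 12153 probes, the position estimated from covariances between arrays was 0.54. Unrelated pools of like spread would give about 0.5, so this value alone shows no relation between them. The r of -0.178 given above, between the ratios of PDGFRα−CAR+ cells over each of the other pools, argues against unrelated pools. A full gradient, with each step at least 2-fold, was shown by 99 probes in the upward and 53 in the downward direction. A further 528 probes passed only between the PDGFRα+CAR+ and PDGFRα−CAR− populations.

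Probes set apart in a single population were mostly those of the outer populations. At least 2-fold above both other populations were 264 probes in PDGFRα+CAR+ cells, and 226 were at least 2-fold below both. With median centring, which left an offset of Cy3 over Cy5, these counts were 127 and 244. In the authors' ratios they were 418 and 503, so their balance depends on processing. In PDGFRα−CAR+ cells 29 probes were at least 2-fold above both other populations and 4 were at least 2-fold below both. These counts became 66 and 0 with median centring, 57 and 24 in the authors' ratios and 166 and 159 with local background subtracted. Simulated array noise alone gave 0 probes in each of these classes, but it holds no difference between pools and is no reference for unrelated pools. The 290 and 306 probes above are the corresponding classes for PDGFRα−CAR− cells, as the highest and the lowest of the populations.

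**Figure D3:**
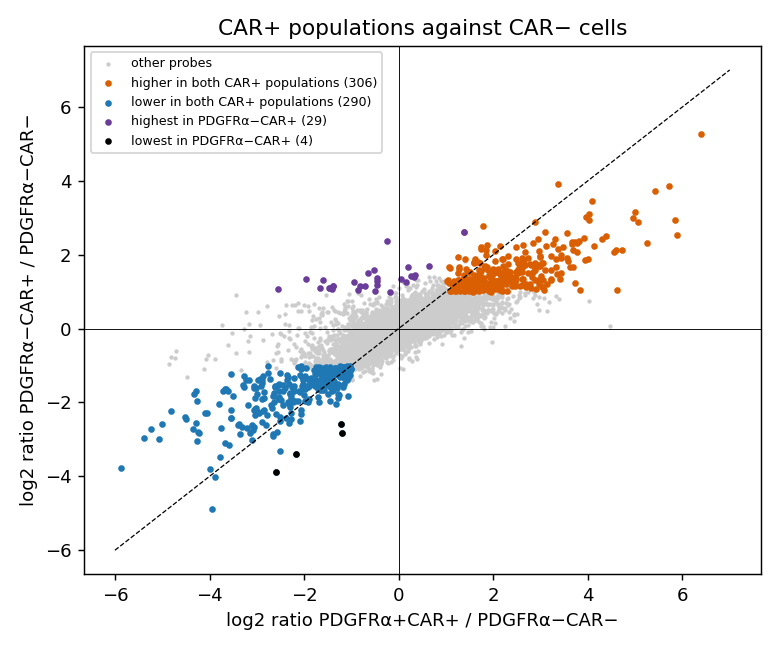
Log2 ratio of each probe in PDGFRα+CAR+ cells (horizontal axis) and in PDGFRα−CAR+ cells (vertical axis), both over PDGFRα−CAR− cells. Coloured points are probes at least 2-fold higher (306) or lower (290) in both CAR+ populations, and probes highest (29) or lowest (4) in PDGFRα−CAR+ cells, drawn last; the dashed line marks equal ratios. Grey points include probes below background.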

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

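The positive control spots, which enter none of the comparisons, had median log2 ratios outside the interquartile range of the negative control spots on every array. That range was narrow, with quartiles of -0.050 and 0.063 on the first array, inside the technical SD of 0.083. A ratio outside it is therefore not unusual by itself. The labels do not say what the positive controls are or whether both dyes received equal amounts. Positive control 2 had medians over 24 spots of -0.20 for PDGFRα−CAR+ over PDGFRα−CAR−, 0.26 for PDGFRα+CAR+ over PDGFRα−CAR− and -0.29 for PDGFRα−CAR+ over PDGFRα+CAR+. Positive control 3 had medians over 24 spots of -0.82, -0.71 and -0.57 in the same order. The 2 controls thus differed from each other on the same array, and neither was used to rescale the probes.

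The 3 patterns weighed here were noticed in these data. The test of the distance between the outer pools was written after the spreads and counts of the arrays had been seen. The simulated mixture, its use in the verdict, the bootstrap interval and the repeats in other settings were added after the difference of -0.41 below was known. The other bounds were set before their values were computed. Set aside afterwards, to keep to 3 patterns, were 2 tests on the loop residual that had been written beforehand. For uneven hybridisation, the medians of 24 print blocks had an SD of 0.020, which is 0.126 of the residual SD of 0.155 and lies between the bounds set beforehand, so it decided nothing. For a dye effect specific to a probe, no dye was swapped, so no value tells it from noise. Its size is limited, because a constant effect would enter the loop residual in full. That residual lay within 0.5 of 0 for 99.5% of the measured probes and reached 1 in size for 5.

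The PDGFRα−CAR+ pool lay between the other pools for most probes that separated them. A pool in which the other 2 populations were mixed, for example by an imprecise sort gate, would give 1 mixing share for every probe on the linear scale. The median share of PDGFRα+CAR+ RNA was 0.33 from 146 probes at least 4-fold higher in PDGFRα+CAR+ cells and 0.74 from 144 probes at least 4-fold lower there. The difference was -0.41 (95% bootstrap interval over probes -0.49 to -0.35), while a simulated equal mixture gave 0.03 from 138 higher and 37 lower probes. The simulation put PDGFRα−CAR− cells at each probe's mean level over the channels, so its lower probes were dimmer than the observed ones. It therefore matches the 144 observed lower probes poorly, and it covers a mixing share of 0.5 only. Probes of 1 pool are not independent replicates, so the interval does not cover array scaling or another pool. The observed difference was -0.37 with an offset of 10, -0.39 without background correction, -0.36 in the authors' ratios, -0.36 with local background subtracted and -0.41 with local normexp. With median centring it was -0.20 (-0.28 to -0.07), on the bound of 0.2 in size set beforehand, in a setting whose loop residual had a median of 0.42 against 0.03 with loess. With loess, and in the authors' ratios, these values argue against a mixture of these 2 populations alone, and median centring leaves it less clear. A mixture that also holds another kind of cell, or a distinct state of the PDGFRα−CAR+ cells, may underlie the values, and neither was tested.

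Some probes were highest or lowest in the PDGFRα−CAR+ pool. There were 33 of them. The simulations hold array noise alone and no difference between separately sorted pools, so with 1 pool per population the count does not decide whether this pool was a mixture of the others, although it passed the bound set beforehand. That reading was made after the count was known. Probes near background as the only source were argued against, since 60.6% of the 33 (20 probes) lay above the median brightness of the measured probes. The offset shrinks the ratios of dim probes, so that share is partly set by the rule, and the values speak for these 20 probes only. The numbers in each direction depended on normalisation and background correction, with 66 highest and 0 lowest under median centring and 166 and 159 with local background subtracted. The number of biological replicates, 1 pool, leaves open whether another pool would show the same probes.

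The PDGFRα+CAR+ and PDGFRα−CAR− pools were farthest apart. Greater noise on that array cannot be the cause, because covariances between arrays, which array noise does not enter, gave an SD 1.52 times that of the next pair among the 4051 brightest probes. That these pools differ in both sorted proteins is a biological difference named by the design, and its contribution was not tested separately.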

How the results depend on the processing

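No paired analysis was possible because each comparison has 1 array and the labels carry no replicate numbers. For the same reason no replicate could be left out. Of 72 recomputed counts of probes at least 2-fold higher or lower, 46 stayed within 1.5 times the reported count. Removing the filter on dim probes changed no count. In the order higher, lower for PDGFRα−CAR+ over PDGFRα−CAR−, for PDGFRα+CAR+ over PDGFRα−CAR−, and for PDGFRα−CAR+ over PDGFRα+CAR+, the authors' ratios gave 705, 607, 1203, 1116, 638 and 476. A normexp offset of 10, chosen after seeing the data, gave 670, 535, 1192, 1022, 516 and 451. Of the probes counted in the report, 608 of 692, 1255 of 1462 and 483 of 574 were counted in the authors' ratios in the same direction and 0 in the opposite one, while 84, 193 and 88 lacked a value there on some array. Subtracting local background gave 1641, 1818, 1378, 1353, 846 and 779. It also raised the technical SD from 0.083 to 0.41 and lowered the correlation between direct and indirect ratios from 0.949 to 0.391. Normexp with local background, also added later, gave 239, 452, 409, 185 and 162 for the counts that moved, with a technical SD of 0.19. Median centring of each array left the measured probes with medians of 0.38, 0.24 and 0.47 and gave 173 lower in the first comparison and 132 lower in the third, with a technical SD of 0.17. Keeping only probes above background in all populations gave 158 lower in the third comparison. Of 66 recomputed counts of probes shared or set apart, 35 stayed within 1.5 times. In the order higher in both CAR+ populations, lower in both, highest in PDGFRα−CAR+, lowest there, highest in PDGFRα+CAR+ and lowest there, the authors' ratios gave 579, 499, 57, 24, 418 and 503. The offset of 10 gave 533, 460, 54, 10, 420 and 402, and subtracting local background gave 685, 624, 166, 159, 483 and 512. Normexp with local background gave 133, 157, 17, 151 and 121 for all but the fourth. Median centring gave 157 lower in both, 66 and 0 highest and lowest in PDGFRα−CAR+, and 127 highest in PDGFRα+CAR+ cells. Keeping only probes above background in all populations gave 146 highest in PDGFRα+CAR+ cells. Probes lowest in PDGFRα−CAR+ cells numbered 8 from the direct arrays alone, 7 by loop least squares and 8 from dye-free ratios. Except where the construction is named, the cause was not tested. The position of the PDGFRα−CAR+ pool ranged from 0.51 to 0.63 over 6 alternatives. The 4 named probes kept their direction in all 120 recomputed ratios, 78 of which moved by more than the technical SD. The sizes moved most for M300004916, with 3.93 (normexp with local background) to 8.64 (subtraction of it) for PDGFRα+CAR+ over PDGFRα−CAR−, and 1.05 with local normexp for PDGFRα−CAR+ over PDGFRα−CAR−. With local normexp, M300004395 had 1.58 and M200016163 had 1.38 for PDGFRα−CAR+ over PDGFRα+CAR+. Alternatives for gene lists, and for genes with several probes, were not run because no probe could be assigned to a gene. Signals close to the blank level limit the ratios of dim probes.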

Other observations

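Signal was unevenly spread over probes in every pool. The 100 brightest probes held 28.3% and 29.4% of the probe signal in PDGFRα−CAR− cells (Cy5), 20.5% and 22.2% in PDGFRα−CAR+ cells (Cy3), and 20.5% (Cy3) and 26.7% (Cy5) in PDGFRα+CAR+ cells. The value for the PDGFRα+CAR+ pool differed between its arrays, which also differ in dye and scan run, by about as much as the pools did, so no order of the populations is read from it. Probes above background in a single population on both of its arrays, and below it in the others, numbered 33 for PDGFRα−CAR−, 476 for PDGFRα−CAR+ and 78 for PDGFRα+CAR+ cells, and dye, array and scan run are not separated from population there. The median loop residual per print block ranged from -0.022 to 0.067 over 24 blocks. The 1 probe with 2 spots per array, M300000682, differed between its spots by 0.19, 0.075 and 0.13 on the log2 scale.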
